A study of Mus musculus with 16 samples.

How the data were processed

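Total RNA of RAW264.7 cells was sequenced with the Lexogen QuantSeq 3′ FWD kit, per the labels' protocols, in 16 libraries that form 4 groups of 4 (control siRNA, Cebpb siRNA, and each with isoproterenol). The labels give 2 experiments with 2 replicates per group each, and the design text calls the 4 libraries of a group biological replicates. Cells were transfected with 25 nM siRNA for 24 h before stimulation, and 1 siRNA product was used against Cebpb. The dose and duration of isoproterenol are not given in the sources used here. Reads were aligned with STAR 2.5.3a to GRCm38, per the submitters' processing notes. The counting tool, and whether it used strand, are not given in the sources used here.

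The values deposited by the authors are on a log2 scale, log2 of reads per 10⁶ sequenced reads of all kinds (RPM), with values of 1 RPM or less listed as 0. This was worked out from the values: multiplying back gave whole reads within a tolerance of 0.1 read for 100% of the listed values, with library totals of 9.42 to 25.17 M reads, of which 5.81 to 15.9 M fell on genes. Summary entries for unmapped, multimapping, ambiguous and unassigned reads stayed out of the tests. A value of 0 therefore means at or under the floor, which corresponds to 9 to 25 reads depending on the library. Differences of genes near the floor are understated, and 1392 of the tested genes were at the floor in at least 1 library.

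Because the values are log2 rather than counts, the planned count test (edgeR, quasi-likelihood) was not used and limma 3.58.1 with a trend and robust estimation took its place. Libraries were scaled by a trimmed mean of log ratios (30% trimmed by ratio, 5% by level), all libraries were given a common floor, and genes above it in at least 4 libraries were kept (11141 genes). The fit had the 4 groups and the experiment as terms, over all 16 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were isoproterenol against none in each siRNA group, Cebpb siRNA against control siRNA without and with isoproterenol, and the difference of the isoproterenol effects. Every adjusted p of a gene comes from limma, and every adjusted p of a list, unless fry is named, from camera in limma with a preset correlation of 0.01, adjusted over 19 lists with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Errors of log2 fold changes are standard errors, and errors of RPM levels are SDs of unscaled values over 4 libraries.

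In all 25 gene lists were written from textbook knowledge: M2 and M1 activation, type I interferon response, cAMP and CREB response, β-adrenergic signalling, the C/EBP family, C/EBPβ-linked myeloid genes, NF-κB targets, osteoclast genes, antigen presentation, cholesterol synthesis, LXR and lipid efflux, glycolysis and hypoxia, the ATF4 stress response, cell cycle, oxidative phosphorylation, lysosome and phagocytosis, macrophage identity, tumour-associated and angiogenic genes, and markers of fibroblasts, epithelial cells, T and NK cells, B cells, neutrophils and dendritic cells. The C/EBPβ-linked list shares 15 genes with other lists and the M2 list 6. The lists, the contrasts, the other settings first tried and the rule for naming genes were chosen before the data were examined. That rule took, for each contrast, genes past the threshold with the same sign in both experiments, a mean of at least 10 RPM and a symbol that is not a provisional gene model or pseudogene, ranked by size: the first 8 up and 8 down, or 5 and 5 for the difference. It added up to 4 members of each described list by smallest adjusted p, and Cebpb, Arg1, Il10, Vegfa, Chil3, Mrc1, Il6, Tnf, Il1b and Nos2.

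Gene names were matched to GENCODE vM21 on GRCm38 for identifiers, coordinates and 3′ UTRs: 49521 of 52636 names (94.08%) matched 1 gene. In the files 106 symbols occur more than once, and 24 names had the form of a date, 14 of them among the tested genes. For genes with near-identical copies (Rps26, the Hist1h genes, Ctla2a and Ctla2b, H2-D1) the assignment of reads is uncertain, as it is for overlapping and antisense genes. The longest annotated 3′ UTR of each gene was searched for words of 7 bases, over 10157 genes, 91.2% of those tested. The sequence of the siRNA is not given in the sources used here.

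The chi-square per degree of freedom between replicates of a group and experiment was 5.16 to 14.2 against counting noise. This does not tell repeated preparations from separate cultures, and the libraries were taken as biological replicates per the labels. Each step was tested on simulated data with the real means: of 100 genes changed by log2 0.5 and 100 by log2 1, the fit recovered 66% and 90% for isoproterenol in control siRNA cells, 72% and 96% for Cebpb siRNA without isoproterenol, 61% and 94% with it, 50% and 87% for the difference, and 68% and 95% for isoproterenol in Cebpb siRNA cells. False calls made up 6.02%, 6.67%, 3.73%, 8.05% and 5.78% of the calls. A list shifted by log2 0.25 had an adjusted p of 2.61e-14, 0 of 99 random lists passed, and a planted word ranked 1st of all words in both comparisons. Its planted log2 difference of −0.2 was estimated at −0.122 without and −0.198 with isoproterenol, so the size can be understated. All simulated groups had the means of control siRNA cells, apart from the changed genes. In the data 60.96% of genes were called for Cebpb siRNA without isoproterenol and 61.56% with it. The rates of recovery and false calls need not hold for those comparisons. The simulated genes were drawn independently and without an experiment effect. The list result therefore says nothing of false calls in lists of correlated genes, where the estimated correlation reached 0.369 (interferon response).

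Alternatives were other scalings, limma-voom on the recovered reads, other filters, no experiment term, a block for the replicate number, only the libraries compared, each experiment alone, no robust estimation, and each library left out in turn. Values as deposited, a higher floor, a pseudocount of 1 RPM, removal of ribosomal and mitochondrial RNA, and restriction to genes without the motif core were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and the R package data.table (version 1.17.8) were used.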

Results

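Gene expression was measured in RAW264.7 cells, a mouse macrophage-like cell line, by 3′ end RNA sequencing, in which reads come from near the polyadenylated end of each transcript. Cells were transfected with a control siRNA or with an siRNA against Cebpb, the gene of the transcription factor C/EBPβ. They were then left without stimulation or given isoproterenol, an agonist of β-adrenergic receptors that raises intracellular cAMP. The title asks whether C/EBPβ controls genes of alternative (M2) activation in macrophages stimulated through these receptors. Each of the 4 groups held 4 libraries, 2 from each of 2 experiments. Library size ranged from 9.42 M reads (Cebpb siRNA, replicate 2 of experiment 2) to 25.17 M, of which 5.81 to 15.9 M were assigned to genes. A total of 11141 genes rose above the floor of 1 RPM (reads per 10⁶ reads) in at least 4 libraries and were tested. The 1st principal component held 68.34% of the variance. It separated Cebpb siRNA libraries (27.78 to 38.97) from control siRNA libraries (−36.68 to −30.19). The 2nd, with 10.64%, separated the experiments.

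Cebpb (ENSMUSG00000056501.3, chromosome 2, 167688915 to 167690418 on the plus strand of GRCm38), the targeted gene, fell to 30.1% of its control level without isoproterenol and to 28.7% with it. Its level was 76.1 ± 11.2 RPM with control siRNA, 22.9 ± 8.83 with Cebpb siRNA, 92.1 ± 10.3 with control siRNA and isoproterenol, and 26.4 ± 2.04 with both (SD, n = 4 each). The log2 fold change was −1.73 ± 0.19 (SE) in both siRNA comparisons (limma adjusted p = 1.98e-07 without and 1.89e-07 with isoproterenol). In an exact two-sided permutation test p was 0.0286 for each, the smallest that 4 against 4 libraries allow. It was 0.0839 after Benjamini-Hochberg adjustment over all such library measures. Isoproterenol changed Cebpb by 0.25 ± 0.19 in control siRNA cells, with the same estimate in Cebpb siRNA cells (adjusted p = 0.715 and 0.51). In unscaled log2 RPM the change was 0.39 and 0.17 in experiments 1 and 2 with control siRNA. With Cebpb siRNA it was 0.71 and −0.11, so an equal response is not shown.

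**Figure D1:**
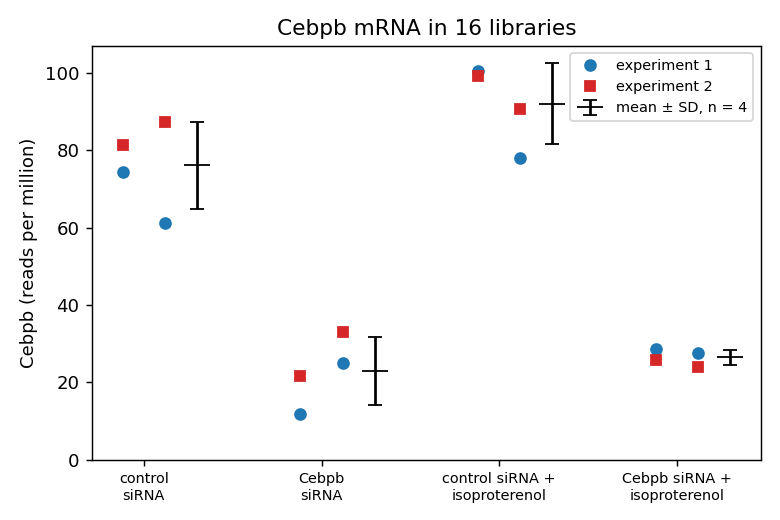
Level of Cebpb in RPM (vertical axis) in each of the 16 libraries, by group (horizontal axis), with the mean and SD of each group. The 8 libraries with Cebpb siRNA lie between 11.8 and 33.1 and the 8 with control siRNA between 61.3 and 100.6.

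Isoproterenol in control siRNA cells raised transcripts of cAMP-induced and myeloid genes and lowered a smaller set. Named by size here and for the other comparisons are genes with a mean of at least 10 RPM. Osbp2, which encodes an oxysterol-binding protein, rose 6.04-fold (log2 2.59 ± 0.12, adjusted p = 7.89e-12), from 3.93 ± 0.644 to 24.2 ± 4.06 RPM (SD, n = 4). Odc1, the rate-limiting enzyme of polyamine synthesis, rose 2.74-fold (log2 1.45 ± 0.12) and Fos, an immediate early transcription factor, 2.72-fold (1.44 ± 0.11). Edil3 (1.69 ± 0.11), Tnfrsf9 (1.24 ± 0.13), Pcdh7 (1.19 ± 0.09), Cd93 (1.04 ± 0.12) and Trem1 (1.04 ± 0.12), a receptor that amplifies myeloid inflammation, completed the 8 largest increases at that level. The 8 largest decreases at that level were Efr3b (−1.37 ± 0.13, adjusted p = 1.15e-06), the C-type lectin Clec12a (−0.80 ± 0.11), lipoprotein lipase Lpl (−0.76 ± 0.07), Ptchd1 (−0.66 ± 0.09), Ints10 (−0.54), Bard1 (−0.50), the histone methyltransferase Dot1l (−0.47) and the linker histone Hist1h1b (−0.46). In all, limma called 131 genes higher and 48 lower, 14 and 1 of them by at least 2-fold. In the same libraries the mitochondrial rRNA mt-Rnr2 went from 18700 ± 1190 to 21390 ± 525 RPM (1.14-fold) and mitochondrial mRNA from 5174 ± 251 to 5701 ± 232 (1.10-fold), each with an exact permutation p = 0.0286, or 0.0839 after adjustment. S100a8, the tested neutrophil marker, also rose, by log2 0.80 ± 0.14 at a mean of 2.03 RPM (adjusted p = 0.00287).

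Among the lists fixed in advance, 6 of 24 tested cAMP and CREB response genes rose and 1 fell (13 and 1 when adjusted over the list alone, camera adjusted p = 1.39e-12). Besides Odc1 and Fos, Crem, a cAMP-responsive transcription factor, rose by log2 0.87 ± 0.10 and Fosl2 by 0.66 ± 0.08. Of 14 myeloid genes linked to C/EBPβ in the literature, 7 rose, Lyz2 (lysozyme, 0.75 ± 0.07), Clec4e (0.55 ± 0.05) and Clec4d (0.55 ± 0.06) among them (8 rose and 1 fell adjusted over the list alone, adjusted p = 7.92e-11). Of 19 macrophage identity genes, 4 rose (10 adjusted over the list alone, adjusted p = 2.35e-09), including Cd14, the lipopolysaccharide co-receptor, by 0.67 ± 0.09. Of 22 genes of classical (M1) activation, 4 rose (7 adjusted over the list alone, adjusted p = 1.16e-05): Cxcl2 (0.75), the costimulatory ligand Cd86 (0.72), the prostaglandin synthase Ptgs2 (0.70) and Il1b. Il1b was listed at 0 in all 4 control siRNA libraries and at 3.92 ± 0.865 RPM with isoproterenol, a log2 difference of 1.79 ± 0.17 against the floor (adjusted p = 1.41e-06). Cell cycle genes moved down: 3 of 34 fell, namely Ccnd1 (cyclin D1, −0.26), Mcm6 (−0.29) and Cdk1 (−0.30), and 12 adjusted over the list alone (adjusted p = 2.57e-12). Those 5 calls held with an estimated correlation. Of 25 glycolysis and hypoxia genes 3 rose, Bnip3 (0.53) and the glucose transporter Slc2a1 (0.45) among them (4 adjusted over the list alone, adjusted p = 1e-04, and adjusted p = 0.058 with an estimated correlation). Of 23 NF-κB targets 2 rose, Ier3 (0.68) and Plek (0.25) (4 adjusted over the list alone, adjusted p = 0.00129, and adjusted p = 0.159 with an estimated correlation). The cholesterol synthesis list was called with 0 of 23 members past the test (1 adjusted over the list alone, adjusted p = 6.79e-04, and adjusted p = 0.145 with an estimated correlation). In the β-adrenergic signalling list only Pde8a rose (0.50), and the median (0.02) and the mean (−0.01) differed in sign (adjusted p = 0.89).

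Genes of M2 activation did not pass as a list by camera, and passed by fry as higher (adjusted p = 0.0281). Fry asks whether members together moved in one direction at all, rather than more than other genes. Of 16, 4 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0936). Il1rn, the interleukin-1 receptor antagonist, rose by 0.59 ± 0.08, the scavenger receptor Msr1 by 0.42 ± 0.06 and the lectin Clec10a by 0.33 ± 0.08, and the β-glucan receptor Clec7a fell by 0.72 ± 0.12. Arg1, Il10, Vegfa, Chil3, Il6 and Nos2 lay at the floor of 1 RPM in all 16 libraries, and Mrc1 exceeded it in 2, reaching 1.34 RPM, so a change of these genes under the floor of the deposited values could not be seen. Tnf did not move (0.00 ± 0.07, adjusted p = 1.0; 49.3 ± 3.34 RPM with control siRNA). The experiments gave 101 calls in experiment 1 alone and 11 in experiment 2 alone, with 45 when no term for the experiment was fitted, 386 when only these 8 libraries entered the fit and 100 to 257 when 1 library was left out. It was 100 and 111 without control siRNA replicates 1 of experiment 1 and 2 of experiment 2. It was 116, 117 and 109 without replicate 2 of experiment 1 and replicates 1 and 2 of experiment 2 with isoproterenol. Values as deposited gave 145 higher and 27 lower.

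Cebpb siRNA without isoproterenol was followed by lower levels of cell cycle genes and higher levels of antigen presentation genes, while the higher level of interferon response genes passed with the preset correlation and by fry but not with an estimated correlation. Cdca7, a cell division gene, fell 11.3-fold (log2 −3.49 ± 0.16, adjusted p = 7.28e-14), from 30.8 ± 3.44 to 2.59 ± 0.441 RPM (SD, n = 4). The nuclear export factor Cse1l fell 9.18-fold (−3.20 ± 0.09) and Mcm3, a subunit of the replicative helicase, 6.68-fold (−2.74 ± 0.10). Tm7sf3 rose 11.5-fold (3.53 ± 0.18, adjusted p = 3.78e-13), from 2.42 ± 0.798 to 25.2 ± 2.32 RPM, and Oas2, an interferon-induced oligoadenylate synthetase, 7.35-fold (2.88 ± 0.16). The other large increases at 10 RPM or more were Mxd4 (2.90), carbonic anhydrase Car2 (2.86), Osbp2 (2.56), Hist1h4i (2.53), Edil3 (2.45) and Bmp2 (2.38). The other large decreases were AC121965.1 (−3.31), Trip13 (−2.63), ribosomal protein gene Rps26 (−2.55), Mybl2 (−2.52) and Pbk (−2.46). In total 3428 genes were higher and 3363 lower, 500 and 738 of them by at least 2-fold, and 6779 of the 6791 had the same sign in both experiments.

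Of 34 cell cycle genes, 33 fell (33 adjusted over the list alone, median log2 −1.27, adjusted p = 7.28e-17), among them Cdc6 (−1.98), Mcm6 (−1.89) and Cdk1 (−1.64). Of 23 genes of the ATF4 stress response, 19 fell and 2 rose (the same counts adjusted over the list alone, median −0.76, adjusted p = 4.97e-06), with the serine and one-carbon enzymes Shmt2 (−2.15) and Psat1 (−1.32) and the cysteine synthesis enzyme Cth (−1.94). Antigen presentation genes rose in 13 of 16 cases (13 adjusted over the list alone, median 0.56, adjusted p = 1.33e-04): Cd74, the invariant chain, by 1.59 ± 0.10, Tapbp by 1.04 ± 0.07 and B2m by 0.82 ± 0.08. Those 3 calls held with an estimated correlation. Type I interferon response genes rose in 34 of 36 cases and 1 fell (34 and 1 adjusted over the list alone, median 1.03, adjusted p = 3.02e-09, and adjusted p = 0.239 with an estimated correlation), Oasl2 (1.99) and Parp14 (1.24) among them. NF-κB targets such as Traf1 (1.89) and Relb (1.24) rose in 17 of 23 cases and 3 fell (17 and 3 adjusted over the list alone, adjusted p = 5.45e-04, and adjusted p = 0.239 with an estimated correlation). In the cAMP and CREB list, 16 of 24 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 5.45e-04, and adjusted p = 0.0703 with an estimated correlation), with Btg2 at 2.03 and Fos at 1.71.

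Of 14 C/EBPβ-linked myeloid genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.0458, and adjusted p = 0.268 with an estimated correlation), with Trem1 up by 2.11 ± 0.12 and the Fc receptor Fcgr1 down by 1.38 ± 0.12. Macrophage identity genes rose in 13 of 19 cases and 3 fell (13 and 3 adjusted over the list alone, adjusted p = 0.0252, and adjusted p = 0.268 with an estimated correlation), the fractalkine receptor Cx3cr1 by log2 −2.33. Cholesterol synthesis genes fell in 11 of 23 cases and 2 rose (11 and 2 adjusted over the list alone, adjusted p = 0.0207, and adjusted p = 0.298 with an estimated correlation), with Hsd17b7 at −2.15. M2 genes moved both ways: 7 of 16 rose, Il1rn (2.29) and Mgl2 (1.31) the most, and 6 fell, Ppargc1b (−1.08) the most (7 and 6 adjusted over the list alone, adjusted p = 0.395 by camera and 1.31e-06 by fry, which called the list higher). M1 genes also split, with 13 of 22 up and 4 down (13 and 4 adjusted over the list alone, adjusted p = 0.0526 by camera and 5.48e-05 by fry, as higher): the costimulatory receptor Cd40 rose by 1.62 and the chemokine Ccl3 fell by 2.32. Il1b rose by 0.96 ± 0.17 against the floor (adjusted p = 6.23e-05), and Tnf differed by 0.09 ± 0.07 (adjusted p = 0.302). Of the other cells' markers, S100a8 (−1.36), the dendritic cell gene Batf3 (−1.99) and the T and NK cell gene Lck (−0.50) fell. Of the 7 C/EBP family genes 2 rose and 5 fell (2 and 5 adjusted over the list alone, adjusted p = 0.348), with Cebpd at 0.85 and Ddit3 at −1.19. The targeted Cebpb is a member of this list and one of those that fell. The mitochondrial rRNA mt-Rnr2 was higher in these libraries (26450 ± 1190 against 18700 ± 1190 RPM), as was the share of unmapped reads (6.96% against 5.45%), each with an exact permutation p = 0.0286, or 0.0839 after adjustment (n = 4 each). The calls numbered 5962 in experiment 1 alone and 4814 in experiment 2 alone, and values as deposited gave 2726 higher and 3917 lower. In all 3824 of 6279 were called when only genes whose 3′ UTR lacks the core of the motif described next were tested, against 6791 of 11141 over all genes.

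**Figure D2:**
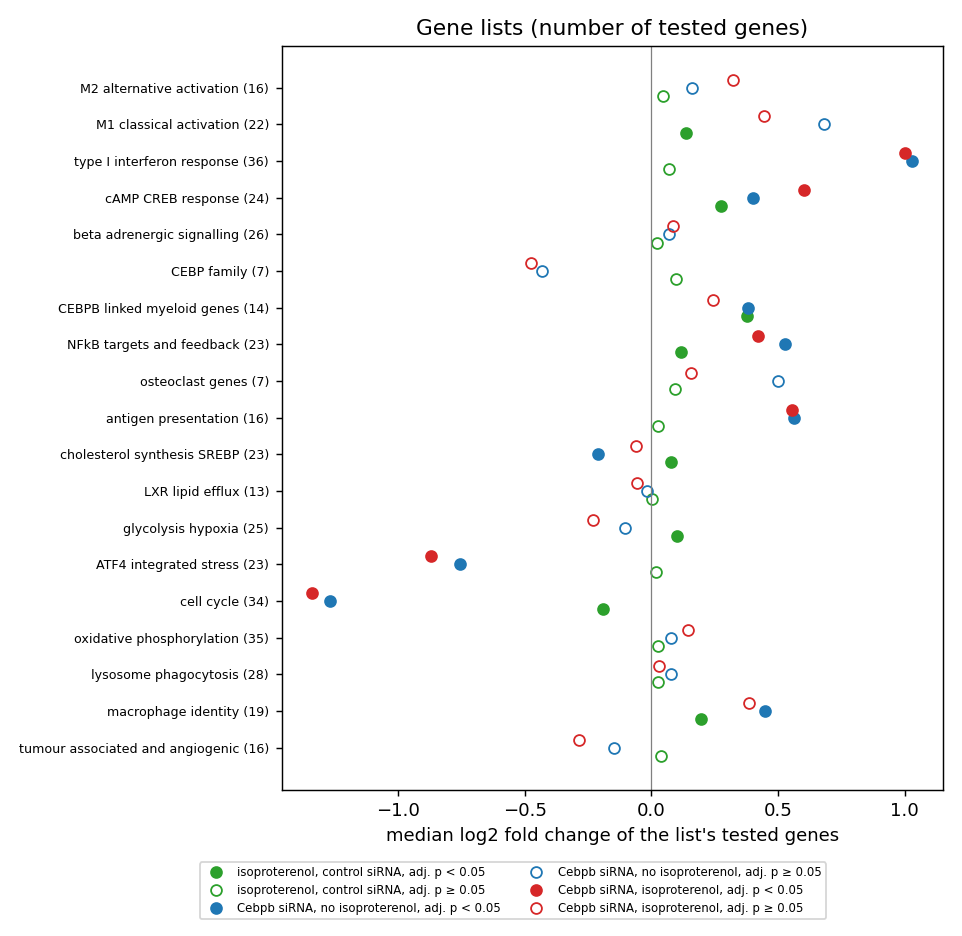
Median log2 fold change (horizontal axis) of the tested genes of each list (vertical axis) for isoproterenol in control siRNA cells and for Cebpb siRNA without and with isoproterenol, with filled points for a camera adjusted p under 0.05. Cell cycle genes lie at −1.27 and −1.34 with Cebpb siRNA, and type I interferon response genes at 1.03 and 1.00.

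The direction of the siRNA effect was related to a short motif in the 3′ UTR. Every 7-base word present in the 3′ UTRs of at least 50 of 10157 genes (16041 words) was compared between genes with and without it. AACTTGT, which occurs once in the Cebpb transcript (chromosome 2, 167689859 to 167689865, outside the 3′ UTR), had the most negative t of all words both without and with isoproterenol (−18.2 and −18.4, adjusted for length and base composition of the 3′ UTR and for the level of the gene), and the log2 difference of its 1523 genes from the others was −0.31 and −0.33. Of the 16041 words, 1078 occur in the Cebpb transcript. The 2nd word, ACTTGTA (−17.6 and −17.4), overlaps the 1st by 6 bases and does not occur in it. The most positive t values were 4.84 and 4.59. Without isoproterenol the median log2 fold change was −0.39 in 449 genes with the 8-base form AACTTGTA, of which 56.6% were called lower, −0.18 in 1074 genes with AACTTGT alone, and 0.07 in 6278 genes without its 6-base core, of which 25.7% were called lower. The median was −0.15 in 711 genes with ACTTGTA but not AACTTGT. It was −7.73e-05 in 1645 genes with the core alone, of which 31.7% were called lower and 31.1% higher. The core alone thus went with little shift. Of the 8 named genes that fell most, 6 held the core in the 3′ UTR (Cdca7, Cse1l, Mcm3, Trip13, Mybl2 and Pbk), against 1 of the 8 that rose most (Mxd4). Mcm3 and Mxd4 held the core alone. Over all 10157 genes 6278 lacked it, and AC121965.1, among those that fell most, has no annotated 3′ UTR. Since the word was found from these same fold changes, the counts are not separate support. The class medians are not adjusted for 3′ UTR length, whose median was 2743 bases with the 8-base form and 774 without the core. The t treats genes as independent and is given as a description, and the division into classes was made after the word had been found.

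**Figure D3:**
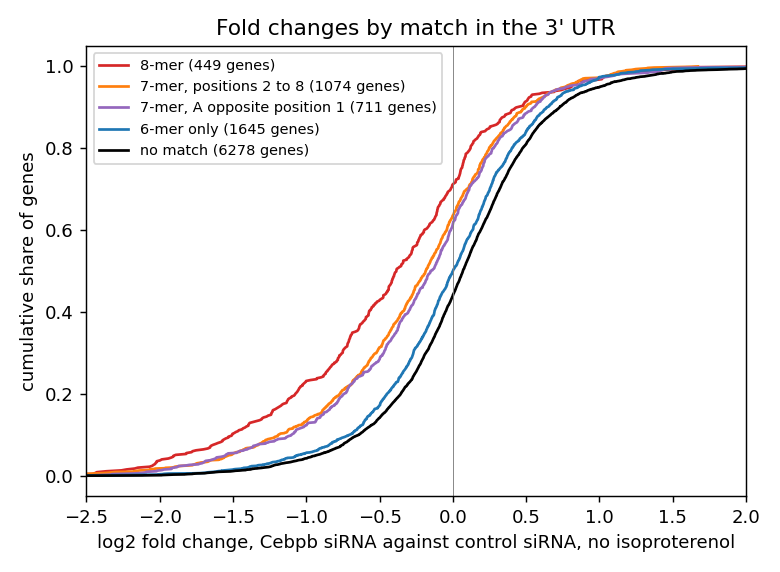
Cumulative share of genes (vertical axis) by log2 fold change with Cebpb siRNA without isoproterenol (horizontal axis), by the match of the 3′ UTR to the word AACTTGT. The median is −0.39 for the 8-base form and 0.07 for genes without the 6-base core.

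Cebpb siRNA in the presence of isoproterenol, the comparison closest to the question in the title, gave 3526 higher and 3332 lower genes, 521 and 769 of them by at least 2-fold. Cdca7 fell 13.2-fold (−3.72 ± 0.16, adjusted p = 2.32e-14), Cse1l 9.72-fold (−3.28 ± 0.09), Mcm3 7.98-fold (−3.00 ± 0.10) and Ccl3, a macrophage chemokine, 6.93-fold (−2.79 ± 0.08). AC121965.1 (−2.96), Trip13 (−2.80), the cell cycle kinase Wee1 (−2.75) and Timeless (−2.61) followed. Tm7sf3 (3.32 ± 0.18), Oas2 (2.97 ± 0.16), Car2 (2.79), the motor protein Myo6 (2.78), the checkpoint receptor Havcr2 (2.73), Hist1h2bc (2.65), Mxd4 (2.58) and Fam46c (2.51) rose most among genes with a mean of at least 10 RPM. Tnf fell by 0.27 ± 0.07 (adjusted p = 0.00254), and Il1b was 0.31 ± 0.17 higher without passing the test (adjusted p = 0.127).

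Of the 16 tested M2 genes, 8 rose and 6 fell (8 and 6 adjusted over the list alone, adjusted p = 0.281 by camera and 2.89e-07 by fry, which called the list higher). Ccl22, a chemokine, was listed at 0 with control siRNA and isoproterenol and at 3.63 ± 0.667 RPM with Cebpb siRNA and isoproterenol. Il1rn rose by 1.65 ± 0.08, Mgl2 by 1.18 ± 0.06 and Clec10a by 1.12 ± 0.08, and Msr1 fell by 0.61 ± 0.06. Among M1 genes 12 of 22 rose and 6 fell (12 and 6 adjusted over the list alone, adjusted p = 0.281), the latter with Marco (−2.27), Acod1, which makes itaconate (−1.96), and Ccl4 (−1.51). Of the C/EBPβ-linked genes 8 rose, Il1r2 (3.10) and Trem1 (2.15) the most, and 4 fell, Fcgr1 (−1.55) the most (8 and 4 adjusted over the list alone, adjusted p = 0.373). Cell cycle genes fell in 33 of 34 cases (33 adjusted over the list alone, median −1.34, adjusted p = 5.32e-17) and ATF4 genes in 18 of 23, with 1 up (18 and 1 adjusted over the list alone, median −0.87, adjusted p = 2.13e-06). Antigen presentation genes rose in 13 of 16 cases (13 adjusted over the list alone, adjusted p = 3.95e-04) and cAMP and CREB genes in 17 of 24, with 2 down, Atf3 (−0.89) being one of them (19 and 2 adjusted over the list alone, adjusted p = 1.83e-04). Interferon genes rose in 29 of 36 cases and 1 fell (30 and 1 adjusted over the list alone, median 1.00, adjusted p = 1.16e-07, and adjusted p = 0.391 with an estimated correlation), and NF-κB targets in 15 of 23, with 4 down (15 and 4 adjusted over the list alone, adjusted p = 0.0144, and adjusted p = 0.42 with an estimated correlation).

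In the lists that follow the counts were the same adjusted over the list alone, except that 2 C/EBP family genes then rose. Macrophage identity (13 of 19 rose, 4 fell, adjusted p = 0.101), cholesterol synthesis (3 rose, 11 of 23 fell, adjusted p = 0.152) and glycolysis genes (6 rose, 12 of 25 fell, adjusted p = 0.243) did not pass by camera here, and passed by fry. The next lists had no call by camera in either siRNA comparison, while fry called the C/EBP family, osteoclast, LXR and tumour-associated lists in both and β-adrenergic and lysosomal genes with isoproterenol. Among LXR and lipid genes lipoprotein lipase Lpl (−1.68) and the fatty acid binding proteins Fabp4 (−2.08) and Fabp5 (−1.60) fell in the presence of isoproterenol (5 of 13 fell, 4 rose, adjusted p = 0.372). Lpl, Fabp4 and Fabp5 hold the motif core in the 3′ UTR, Lpl as the core alone. The median of this list was −1.6 in the 5 genes with the core and 0.07 in the 8 without. Cell cycle genes had −1.52 and −1.2, and cholesterol synthesis genes, in the reverse order of size, −0.0572 and −0.222. Tumour-associated and angiogenic genes (4 of 16 rose, 8 fell, adjusted p = 0.297) held Cxcr4 (1.83) and Csf1 (−2.16). Osteoclast genes (3 of 7 rose, 1 fell, adjusted p = 0.281) held Car2 and Dcstamp (0.96). Oxidative phosphorylation genes (14 of 35 rose, 7 fell, adjusted p = 0.335) held Ndufs1 (0.81) and Ndufv2 (−1.08). β-adrenergic signalling genes (11 of 26 rose, 7 fell, adjusted p = 0.335) held the protein kinase A subunits Prkacb (1.06) and Prkar2a (−2.31). Lysosomal genes (11 of 28 rose, 10 fell; median 0.03, mean −0.09, adjusted p = 0.973) held Gpnmb (−1.67). C/EBP family genes (1 of 7 rose, 4 fell, adjusted p = 0.281) held Cebpg (−0.48). They include the targeted Cebpb, whose fall is part of the counts and fry calls of this list. Markers of other cells were scarce: no fibroblast, epithelial or B cell marker was tested. The T and NK cell marker Lck (−0.98), the neutrophil marker S100a8 (−2.16) and the dendritic cell markers Batf3 (−1.69) and Zbtb46 (0.32) had mean levels under 5 RPM. The rRNA mt-Rnr2 rose from 21390 ± 525 to 32050 ± 4950 RPM and unmapped reads from 5.39% to 6.63% (exact permutation p = 0.0286, or 0.0839 after adjustment, n = 4 each).

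The siRNA effects without and with isoproterenol shared 5903 called genes, 5900 with the same sign, where 2091 were to be found in the same direction if the calls were independent. Across genes the log2 fold changes had a correlation of 0.951, and of 0.893 and 0.894 when each came from a different experiment. Genes are not independent replicates. The counts with isoproterenol were 6109 in experiment 1 alone and 5094 in experiment 2 alone. The count was 3868 of 6279 when only genes lacking the motif core in their 3′ UTR were tested, against 6858 of 11141. Values as deposited gave 2976 higher and 3761 lower.

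Isoproterenol in Cebpb siRNA cells raised 336 genes and lowered 274, with 32 and 4 at least 2-fold. Cytip, a regulator of leukocyte adhesion, rose 4.52-fold (2.18 ± 0.12, adjusted p = 1.23e-10), Osbp2 2.31-fold (1.21 ± 0.12) and Odc1 2.31-fold (1.21 ± 0.12), and Eno3 (1.19), Gpc1 (1.18), S100a11 (1.15), Tgfbi (1.14) and Edil3 (1.11) followed among genes with a mean of at least 10 RPM. Efr3b (−1.50 ± 0.13), Lpl (−1.18 ± 0.07), Ptchd1 (−0.97), Wee1 (−0.80), Ighm (−0.70), Ung (−0.68), Hist1h1b (−0.65) and Plk2 (−0.62) fell most at that level. Mitochondrial mRNA went from 5047 ± 113 to 6283 ± 295 RPM (1.24-fold, exact permutation p = 0.0286, or 0.0839 after adjustment). The cAMP and CREB list rose with 10 of 24 genes (12 up and 1 down adjusted over the list alone, adjusted p = 1.2e-10), led by the orphan nuclear receptors Nr4a2 (2.12 ± 0.14) and Nr4a1 (1.44 ± 0.14, mostly at the floor without isoproterenol) and by Crem (1.09). The cell cycle list fell further, with 14 of 34 genes down (20 down and 1 up adjusted over the list alone, median −0.25, adjusted p = 1.7e-11), E2f1 (−0.46) and Ccne1 (−0.53) among them. Both calls held with an estimated correlation. Macrophage identity genes, including the complement genes C1qa (0.64) and C1qb (0.46), rose in 7 of 19 cases (10 up and 2 down adjusted over the list alone, adjusted p = 1.47e-04, and adjusted p = 0.103 with an estimated correlation). Cholesterol synthesis genes such as Hmgcs1 (0.30) and Msmo1 (0.28) rose in 5 of 23 cases (10 adjusted over the list alone, adjusted p = 1.67e-05, and adjusted p = 0.103 with an estimated correlation).

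C/EBPβ-linked genes rose in 3 of 14 cases and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.00779, and adjusted p = 0.145 with an estimated correlation), and β-adrenergic signalling genes in 2 of 26, Adcy7 (0.28) and Crtc3 (0.40) (2 adjusted over the list alone, adjusted p = 0.0361, and adjusted p = 0.135 with an estimated correlation). M2 genes had 4 of 16 up, Klf4 (0.78) and Ccl22 (1.23) among them, and 2 down, Clec7a (−0.98) among them (4 and 2 adjusted over the list alone, adjusted p = 0.0972 by camera and 0.00583 by fry, which called the list higher). In the M1 list Il1b rose (1.14 ± 0.17, adjusted p = 2.54e-04) while Tnf (−0.35 ± 0.07, adjusted p = 0.00386) and Ccl4 (−0.55 ± 0.06) fell, and the list did not pass (3 up, 5 down, and 5 each adjusted over the list alone, adjusted p = 0.868). The calls numbered 230 and 133 in experiments 1 and 2 alone, 196 without a term for the experiment, 243 with only these 8 libraries, 387 with a floor of 5 RPM and 348 among the 6279 genes lacking the motif core. Values as deposited gave 455 higher and 153 lower, and upper quartile scaling 273 and 325.

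The difference between the isoproterenol effects with Cebpb siRNA and with control siRNA passed the test in 24 genes, 12 in each direction, and 702 had an unadjusted p under 0.05. Larger with Cebpb siRNA was the effect on Cytip (difference of log2 fold changes 1.39 ± 0.16, adjusted p = 0.0001), which went from 4.91 to 8.67 RPM with control siRNA and from 9.89 to 45.7 with Cebpb siRNA. So was the effect on Neurl3 (0.70 ± 0.13, adjusted p = 0.0115), a ubiquitin ligase gene. Lower with Cebpb siRNA was the effect on Osbp2 (−1.38 ± 0.17, adjusted p = 1.35e-04), Acod1 (−0.99 ± 0.18), Pcdh7 (−0.88 ± 0.12), the secreted protease inhibitor Slpi (−0.87 ± 0.13) and lysozyme Lyz2 (−0.74 ± 0.09, adjusted p = 1.35e-04). Lyz2 went from 656 ± 155 to 1110 ± 111 RPM with control siRNA and from 632 ± 38.3 to 664 ± 80.6 with Cebpb siRNA (SD, n = 4). Slpi went from 62.0 ± 2.95 to 94.6 ± 7.95 RPM and from 26.4 ± 6.03 to 22.1 ± 3.44.

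Of the other 17 genes, 8 were named as members of lists (Nr4a2, Nr4a1, Il1r2, Ccl22, Ccl4, Il1rn, Cebpd and Clec4e). The other 9 (Ctla2a, Ppbp, Gfod1, Ramp3, Ctla2b, Dmpk, Ccl9, Cdr2 and Gpr84) were chosen after their values were seen. Nr4a2 rose from 3.84 ± 0.774 to 17.0 ± 0.25 RPM with Cebpb siRNA and had 3.29 ± 0.654 and 4.25 ± 0.193 RPM with control siRNA (difference 1.76 ± 0.20, adjusted p = 6.9e-05). Ctla2a, Ppbp, Il1r2, Gfod1, Ramp3, Nr4a1, Ctla2b, Dmpk and Ccl22 also had a larger effect and lay at the floor in at least 1 library. The effect was also lower, that is less positive or negative, for the chemokines Ccl4 (−0.57 ± 0.09) and Ccl9 (−0.46 ± 0.07), the interleukin-1 receptor antagonist Il1rn (−0.65 ± 0.11), Cebpd (−0.62 ± 0.13), Cdr2 (−0.51 ± 0.10), Gpr84 (−0.44 ± 0.09) and Clec4e (−0.37 ± 0.08). Of the 12 genes with a lower effect, 8 rose with isoproterenol in control siRNA cells, and Ccl4, Acod1, Cdr2 and Gpr84, which did not pass there, fell with it in Cebpb siRNA cells (Ccl4 from 303 to 215 RPM). Reads of Ctla2a and Ctla2b, which are close paralogs, cannot be told apart with certainty. The difference for Cebpb itself was 0.00 ± 0.27, for Tnf −0.35 ± 0.10 (adjusted p = 0.252) and for Il1b −0.65 ± 0.25 (adjusted p = 0.557).

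M1 genes had the lowest adjusted p of the lists for this difference: 2 of 22, Acod1 and Ccl4, were lower (1 higher and 8 lower adjusted over the list alone, adjusted p = 1.25e-05, and adjusted p = 0.0629 with an estimated correlation). Camera also called C/EBPβ-linked genes (1 higher, 2 lower of 14, and 1 and 5 adjusted over the list alone, adjusted p = 0.00245), NF-κB targets (0 of 23, 3 lower adjusted over the list alone, adjusted p = 0.00245), glycolysis genes (0 of 25, 2 lower adjusted over the list alone, adjusted p = 0.00245) and lysosomal genes (0 of 28, 2 lower adjusted over the list alone, adjusted p = 0.016) lower. It called β-adrenergic signalling genes higher and ATF4 genes lower (each adjusted p = 0.0239, with 0 members past the test and 0 adjusted over the list alone). All 7 calls were lost with an estimated correlation, and fry called 3 of them (M1, C/EBPβ-linked and lysosomal genes). After the M1 list they had, in the order named, adjusted p = 0.142, 0.247, 0.157, 0.142, 0.142 and 0.161 with an estimated correlation. M2 genes showed no call (1 of 16 higher, 1 lower, and 2 each adjusted over the list alone, adjusted p = 0.657). In the cAMP and CREB list Nr4a1 and Nr4a2 were higher, and the median (−0.01) and the mean (0.10) differed in sign (adjusted p = 0.33). The difference was called in 5 genes in experiment 1 alone, in 1 gene in experiment 2 alone and in 10 (9 higher, 1 lower) without a term for the experiment. Values as deposited gave 13 higher and 8 lower, and a pseudocount of 1 RPM 5 higher and 12 lower.

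**Figure D4:**
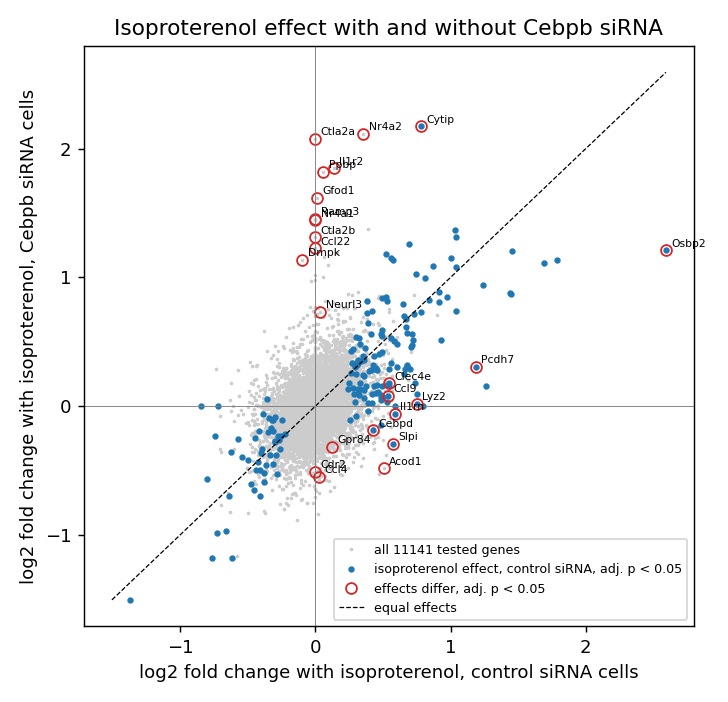
Log2 fold change with isoproterenol in Cebpb siRNA cells (vertical axis) against that in control siRNA cells (horizontal axis) for the 11141 tested genes, with the genes whose effects differed marked. Across genes the correlation is 0.439.

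Of the 131 genes that rose with isoproterenol in control siRNA cells, 75 also rose in Cebpb siRNA cells, none fell there, and 122 had the same sign. Of the 48 that fell, 31 also fell. Genes were picked by their isoproterenol effect in one siRNA group in one experiment and measured in both groups in the other. Picked in control siRNA cells of experiment 1, the mean effect of the 80 genes picked as higher was 0.67 ± 0.41 (SD across genes) with control siRNA and 0.52 ± 0.48 with Cebpb siRNA, or 77.9% of it. That of the 21 genes picked as lower was −0.42 ± 0.26 and −0.47 ± 0.46, or 112%. Picked in experiment 2, 11 genes kept 61.5% in experiment 1. Picked in Cebpb siRNA cells instead, 154 genes of experiment 1 had a mean effect of 0.36 ± 0.41 with control siRNA and 0.60 ± 0.55 with Cebpb siRNA, or 163%. The 97 genes of experiment 2 had 167%. The 76 and 36 genes picked as lower there had 168% and 140%. The share thus depended on the group used for picking, and no smaller or larger response of the genes as a whole was established. The genes that rose with isoproterenol in control siRNA cells were also called higher with Cebpb siRNA in the presence of isoproterenol in 90 cases (68.7%, against 41.46 genes if independent) and lower in 24 cases (39.18 if independent). Those that fell with isoproterenol were called lower in 21 cases and higher in 15 (14.36 and 15.19 if independent). Both comparisons use the same control siRNA libraries with isoproterenol. Across genes the correlation was 0.184 against −0.499 in simulated unchanged groups that shared them, and the covariance 0.02 against −0.00787. With the isoproterenol effect from experiment 1 and the siRNA effect from experiment 2, 47 of 80 genes were higher in both (17.99 if independent).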

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

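Chosen only after the results were seen were the tests of scaling, of the seed match as the direct cause, of the floor in each direction, of a 3′ UTR property and of 3′ UTR length and base composition, and the 2 counts of sample splits for the siRNA comparisons.

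The difference between the isoproterenol effects, tested as an interaction, singled out 24 genes. The log2 differences were 2.08 for Ctla2a, 1.76 for Ppbp, 1.76 for Nr4a2, 1.71 for Il1r2, 1.6 for Gfod1, 1.45 for Ramp3, 1.44 for Nr4a1, 1.39 for Cytip, 1.31 for Ctla2b, 1.23 for Dmpk, 1.23 for Ccl22 and 0.699 for Neurl3, all with a larger effect in Cebpb siRNA cells. With a lower effect, less positive or negative, they were −1.38 for Osbp2, −0.99 for Acod1, −0.882 for Pcdh7, −0.867 for Slpi, −0.736 for Lyz2, −0.646 for Il1rn, −0.617 for Cebpd, −0.575 for Ccl4, −0.507 for Cdr2, −0.455 for Ccl9, −0.442 for Gpr84 and −0.37 for Clec4e.

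For these 24 genes, 3 of 100 sets with permuted residuals, the real one included, called as many genes. The highest other set called 509, far above the real 24, and the reason was not tested. Since permuted sets can call so many genes, the share of sets cannot decide whether chance gave the 24, and chance stays open. The floor accounts for none of the lower effects, since 0 of those 12 genes had a library there, and a higher start that leaves less room to rise is excluded as the whole cause, since 5 genes were called lower with Cebpb siRNA before isoproterenol: Slpi, and Ccl4, Acod1, Gpr84 and Cdr2, which were not called higher in control siRNA cells and fell in Cebpb siRNA cells. It is also excluded for Lyz2, whose start differed by log2 0.06 ± 0.07 against −0.74 for the effect, and stays open for the 6 called higher before it. For the larger effects the floor stays open, because 9 of those 12 genes (not Nr4a2, Cytip and Neurl3) had at least 1 library there, in a prediction that was divided by direction after the result for all 24 fell between its bounds. A dependence of the rise of Slpi and Lyz2 on C/EBPβ, which the design names, may remain as a hypothesis beside an effect of the siRNA on other genes. Ccl4, Acod1, Gpr84 and Cdr2 were not called in control siRNA cells, which does not show that they had no response there. Their mean levels with control siRNA went from 617 to 640, 14.8 to 21.1, 51.6 to 57.6 and 32.1 to 32.7 RPM. They were called lower with isoproterenol in Cebpb siRNA cells, and whether their difference depends on C/EBPβ was not tested.

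In all 6791 genes without and 6858 with isoproterenol differed between Cebpb siRNA and control siRNA cells. The scaling of libraries is argued against, since the lowest count under 3 other scalings was 6643, and so is chance: 1 of 34 splits gave as many genes, the real one with 6616 and the highest other with 0 without isoproterenol, and likewise 1 of 34 with it (6849 against 0). A match of the siRNA's seed to 3′ UTRs is a candidate explanation for part of the change, since the most negative of 16041 words was one of the 1078 that occur in the Cebpb transcript (t = −18.2, against 4.84 for the most positive of any word), in a test whose prediction was written before. Length and base composition of such 3′ UTRs are argued against, since without adjustment the lowest t of 405 other words of the same bases was −4.07 against −19.5. A property that also acts without the siRNA stays open. For isoproterenol in control siRNA cells the word had t = −0.704, rank 4075 from the lowest, where all words spanned −3.83 to 4.3. Only 179 genes were called there, and whether so few could show such a property was not tested. As the direct cause at every called gene a match in the longest annotated 3′ UTR is excluded, since 3835 called genes have one without the 6-base core. Of these, 2219 were higher, for which a lowering by a match was no candidate from the start, and 1616 lower. Matches elsewhere in the transcripts were not searched. For the 3835 genes a loss of C/EBPβ and indirect effects of seed-matched genes stay open with a single siRNA.

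Genes that rose with isoproterenol in control siRNA cells were often also higher with Cebpb siRNA alone: 97 of 131 were called higher and 17 lower, where 40.31 and 39.54 would be so if independent. The correlation across genes, 0.308, was below the 0.498 of simulated unchanged groups that share the control libraries, while the covariance, 0.0323, was above their 0.00785, and the correlation was 0.191 and 0.222 with the effects from different experiments, which share none. Shared control libraries are argued against as the whole cause, since genes picked in one experiment exceeded all tested genes in the share higher with Cebpb siRNA in the other experiment by at least 30.3 percentage points. A difference between wells is argued against by a median isoproterenol effect of at least 0.559 in the experiment not used for picking. A loss of C/EBPβ and another effect of the siRNA stay open as hypotheses, and neither was tested.

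For the isoproterenol calls themselves, 1 of 34 splits gave as many genes in control siRNA cells (386 against 0 at most elsewhere) and 1 of 34 in Cebpb siRNA cells (243 against 1). Without a term for the experiment, the split that parts the experiments gave 2555 and 956 genes against 40 and 70, so 2 of 35 splits were as large.

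Single libraries stood apart in 5 of 129 groups examined, where chance gives about 1 in 20, or 6.45. Nr4a2 stood at 4.27 RPM in 1 control siRNA library (others 2.89 to 3.08), at 4.99 in 1 Cebpb siRNA library (others 3.3 to 3.54) and at 4.54 in 1 library of control siRNA with isoproterenol (others 4.14 to 4.16). Clec4e stood at 352 RPM in 1 library of Cebpb siRNA with isoproterenol (others 325 to 328), and 21.9% of reads were multimapping in 1 library of control siRNA with isoproterenol (others 21.3% to 21.4%). Unmapped reads belong to no gene but count in the total that RPM divides by. They made up 6.96% with Cebpb siRNA against 5.45% in its control and 6.63% against 5.39% with isoproterenol.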

How the results depend on the processing

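Tests chosen only after the results were seen were those on values as deposited, with a floor of 5 RPM, with a pseudocount, without ribosomal and mitochondrial RNA, on genes without the motif core and on genes picked in Cebpb siRNA cells. No called gene shared with the full fit changed sign under any alternative. The DESeq2 Wald test was not run, since reads at or under the floor cannot be recovered; limma-voom was run with those set to the floor. Isoproterenol in control siRNA cells (179 genes) gave 45 without an experiment term, 386 with only the compared libraries, and 101 and 11 in experiments 1 and 2 alone. Leaving out 1 library gave 100 to 257, with 100 and 111 without control siRNA replicates 1 of experiment 1 and 2 of experiment 2, and 116, 117 and 109 without replicate 2 of experiment 1 and replicates 1 and 2 of experiment 2 with isoproterenol. In Cebpb siRNA cells (610) the counts were 196, 243, 230 and 133 under the same settings, 387 with a floor of 5 RPM, 348 of 6279 genes without the motif core and 433 to 587 without 1 library. The difference (24, 12 in each direction) gave 10 without an experiment term (9 higher, 1 lower), 17 with a pseudocount (5 and 12, 14 of them shared), 22 with a floor of 5 RPM (13 shared), 5 and 1 in the experiments alone, and 18 to 27 without 1 library. The Cebpb siRNA counts were 3824 and 3868 of the 6279 genes without the motif core, a share close to that of 6791 and 6858 of 11141. They ranged from 6342 to 6881 and from 6414 to 7108 without 1 library. The share of the isoproterenol response kept with Cebpb siRNA, 77.9% and 61.5% for genes picked as higher in control siRNA cells, was 163% and 167% for genes picked in Cebpb siRNA cells, since the group used for picking is favoured. Single experiments and subsets hold fewer libraries or genes, and the cause of the other changes was not tested. Camera called 8, 9, 6, 7 and 6 lists (isoproterenol in control siRNA cells, the siRNA without and with isoproterenol, the difference, isoproterenol in Cebpb siRNA cells). An estimated correlation left 5, 3, 4, 0 and 2. Fry, which tests another hypothesis, gave 11, 15, 17, 3 and 7, with the M2 list gained as higher in all but the difference, and genes without the motif core gave 4 for the difference and gained the M2 list for isoproterenol in both groups. The replicate block gave 153, 6714, 6772, 28 and 539 genes in the same order. Replicate numbers do not pair the libraries, with correlations of −0.191 to 0.23. Genes under 1 RPM are hidden by the floor of the deposited values, which stands for 9 to 25 reads, and not by depth.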

Other observations

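Apart from the division by the motif core, no tests of this part were chosen after the results were seen. Some lipid and lysosomal genes moved with isoproterenol in control siRNA cells, in both directions. Camera called neither list, and fry called the lysosomal one (adjusted p = 0.0281). Abca1, which exports cholesterol, rose by log2 0.75 (adjusted p = 0.00138) and the lipid droplet protein Plin2 by 0.36, while Lpl fell by 0.76 (list adjusted p = 0.222). The lysosomal protease Ctsl rose by 0.43 and the acid lipase Lipa fell by 0.33 (list adjusted p = 0.0758). Spp1 (osteopontin) rose by 0.49, the stress gene Ddit4 by 0.58 and Cebpd by 0.43 (adjusted p = 0.0134).

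Cebpb siRNA without isoproterenol lowered the growth factors Csf1 (log2 −1.73) and Igf1 (−1.23) and raised the chemokine receptor Cxcr4 (1.41) and Pdgfa (1.27). Within β-adrenergic signalling, Prkar2a fell by 2.44 while Prkacb rose by 1.15, Creb1 by 0.84 and Adcy7 by 0.82, with a median of 0.07 and a mean of −0.03 over the list (adjusted p = 0.603). The lipid binding genes Fabp4 (−1.53) and Fabp5 (−1.29) fell. Osteoclast genes Dcstamp (1.49) and Mmp9 (0.77) rose and Ostm1 fell (−0.58). Lysosomal genes had a median of 0.08 and a mean of −0.01 (adjusted p = 0.499), with Gpnmb (−1.53) and the oxidase subunit Cybb (−0.86) lower. Of the genes named here, the lowered Csf1, Igf1, Prkar2a, Fabp4, Fabp5, Ostm1 and Cybb hold the motif core in the 3′ UTR. So do the raised Prkacb, Creb1 and Adcy7, the last as the core alone. The lowered Gpnmb and the raised Cxcr4, Pdgfa, Dcstamp and Mmp9 lack it. The median of the LXR list was −1.27 in genes with the core and 0.04 in those without. The tumour-associated list had −0.77 and 0.07. The gap was smaller in the cell cycle list (−1.6 and −1.18), where 23 of 24 genes without the core fell. It was reversed in the cholesterol synthesis list (−0.175 with the core and −0.3 without). Whether a match or a loss of C/EBPβ lowered the genes named here was not tested.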
